A study of Mus musculus with 11 samples.

How the data were processed

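DNA was extracted from pancreatic tumours of mice given 5 mg tamoxifen on 3 days at 8 to 10 weeks of age and, per the labels' protocols, aged until morbidity. Libraries were made with a linked-read exome kit and captured with a mouse all-exon bait set. The submitters' processing notes name GATK, HISAT2 2.0.4 and the builds mm10 and GRCm38, without their order or role. The caller, its filters and any normal tissue used for subtraction were not stated there.

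One variant table was used, with a record per variant, tumour and gene. Per the file headers, the deposited depth (DP) is in counts, the reads covering a site, and the deposited allele fraction (AF) is a fraction estimated from those reads, printed here in percent. Per the file headers, the other deposited columns (unit: other) hold reference and variant reads as pairs of counts, the same reads by read-pair orientation, the position, the number of samples with the same variant, and the authors' marks for poor mappability and cancer genes. Reference and variant reads summed to the depth in all 739 records, depth was at least 10 reads, variant reads at least 2 and allele fraction at least 25%. The number of samples with the same variant was 1 throughout. Of the 739 records, 4 repeated a variant under an overlapping gene model and 727 fell inside the RefSeq span of their gene. Mappability and cancer gene marks were present for 631 records and empty for the 108 records of KT tumours 2, 3 and 7. With 10 reads at a site, a fraction is imprecise, and intervals (Wilson, 95%) cover counting error only. No copy number values and no silent variants were in the table used, so the planned copy number comparison and the alternative without silent substitutions were not run.

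Tumours were grouped by genotype, 7 KT and 4 KPT, with 1 value per animal. Numbers in the sample titles are not stated to pair animals, so no pairing was used. Counts, substitution shares (strands folded to 6 classes), indel shares and median allele fractions were compared by exact two-sided permutation of the group means over all 330 splits. Genes with variants in at least 2 tumours, and 12 gene lists with 291 genes, were compared by two-sided Fisher's exact test on tumours with a variant, adjusted by Benjamini-Hochberg. The smallest p this design gives per gene, 7 of 7 against 0 of 4, is 0.0030. Shared genes were compared with 100000 uniform draws from the listed genes and 10000 draws from 21631 coding genes. The first pool holds only genes already listed, which raises its expected number and fixes a shortfall against it in advance. Comparisons, lists, most alternatives and the naming rule were fixed before the data were examined. That rule named list genes with a variant (very long genes: the 5 in most tumours), up to 15 other genes in at least 2 tumours, up to 5 genes per direction by Fisher p, and up to 5 per group by allele fraction, 40 genes in all. The truncating genes, the genes with a cancer gene mark and the genes outside runs with at least 5 variant reads were chosen after their values were seen.

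Runs were defined after seeing the data as at least 3 positions of 1 tumour with gaps of at most 2 Mb, and limits of 1 and 5 Mb were also computed. The limits of 3 and 5 variant reads used to describe runs and C-to-A calls were also set after seeing the data, although a minimum of 5 variant reads was itself set beforehand. The exclusion of KPT tumours 3 and 4, for low depth at their listed sites, was set after seeing the data too. Other settings chosen beforehand were leaving out each tumour, removing multigene families, minimums for allele fraction (10% and 20%), depth (20 reads) and variant reads (5), medians in place of means, a log2 scale with pseudocount 1, a replicate block and other draws. Added ones were leaving out runs, leaving out runs and calls under 5 variant reads, 1 record per gene, leaving out KPT tumours 3 and 4, and a uniform draw over coding genes.

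The tests were tested on simulated data. The permutation test called 5% of 300 unchanged simulations and 99% of those shifted by 3 SD. Its simulated groups had equal spread, unlike the loads here (SD 81.5 and 24.7), so the 99% does not give the power for smaller differences. Fisher's test gave all 10 planted genes (7 of 7 against 0 of 4) an unadjusted p under 0.05, which was fixed by construction. After adjustment over the 204 simulated genes in at least 2 tumours, against 14 such genes in the data, 0% of the planted genes passed. Planted segments were found in runs at 100%, and 0.909% of randomly placed variants were. The simulated tumours held fewer random genes than the 166 genes of KT tumour 1, and planted segments held more variants than the smallest runs. At the data's own gene numbers, random genes put a mean of 30.6 of 572 tumour-gene pairs in runs of at least 3 genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.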

Results

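Exome variants were examined in 11 pancreatic ductal adenocarcinomas that arose from acinar cells of mice. The engineered alleles common to all mice, a tdTomato reporter among them, were switched on in acinar cells by a tamoxifen-activated Cre recombinase under Ptf1a control. The 7 KT tumours had these common alleles alone. The 4 KPT tumours also had floxed alleles of Trp53, the gene for the p53 tumour suppressor. Genotypes with floxed Cdkn2a-Arf, which the series design names as well, were not analysed here, and neither were the engineered loci. The comparison asked how the protein-altering variants listed for each tumour differed between the genotypes.

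The table held 739 variant records in 558 genes, on mouse build GRCm38. Of these, 702 were missense changes, 17 were frameshifts, 8 gained a stop codon, 7 were in-frame insertions, 4 were in-frame deletions and 1 removed a start codon. Depth at a listed site ran from 10 to 198 reads, and the median per tumour was 32, 15, 41, 33, 21, 18 and 58 reads in KT tumours 1 to 7 and 38, 23, 11 and 13 reads in KPT tumours 1 to 4. The listed allele fraction, an estimate of the share of a site's DNA carrying the variant, ran from 25% to 98.7%. Variants at lower listed fractions were therefore not visible, and the total depth of each library is unknown. With few reads the estimate could depart from the share of variant reads in either direction. In KPT tumour 3, Jak1 P866H had 20% variant reads and was listed at 30%, and Fas Q260K had 27.3% and was listed at 25%.

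Most variants sat close together on a few chromosomes of 1 tumour, and they made up the largest loads. KT tumour 1 held 225 records, 29 of them in a stretch of chromosome 15 from 80923574 to 86033119 that includes Ep300, a histone acetyltransferase gene. KT tumour 3 held 92, among them 26 between 37711428 and 39820320 and 35 between 42971205 and 46211878 on chromosome 9. KT tumour 5 held 133, with 13 between 31073236 and 36485384 on chromosome 5. KT tumours 2, 6 and 7 had 13, 6 and 3 records and no such stretch. KT tumour 4 held 79 records, and KPT tumours 1 to 4 held 19, 34, 63 and 72.

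The mean load was 78.7 ± 81.5 records in KT tumours (SD, n = 7) and 47 ± 24.7 in KPT tumours (SD, n = 4), a difference of 31.7 that lay within the spread between tumours (exact two-sided permutation p = 0.512 over 330 splits). All records altered protein, so the protein-altering load was the same number. With the clustered stretches left out, a choice made after seeing the data, the direction turned, to 14.9 records in KT and 30.8 in KPT tumours (exact permutation p = 0.203), and with calls under 5 variant reads left out too it turned back, to 10 and 6.75 (exact permutation p = 0.591). The difference was -0.22 on the log2 scale and 7.33 records without KT tumour 1, but 52 records with at least 5 variant reads (72 and 20, exact permutation p = 0.218) and 52.2 without KPT tumours 3 and 4.

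**Figure D1:**
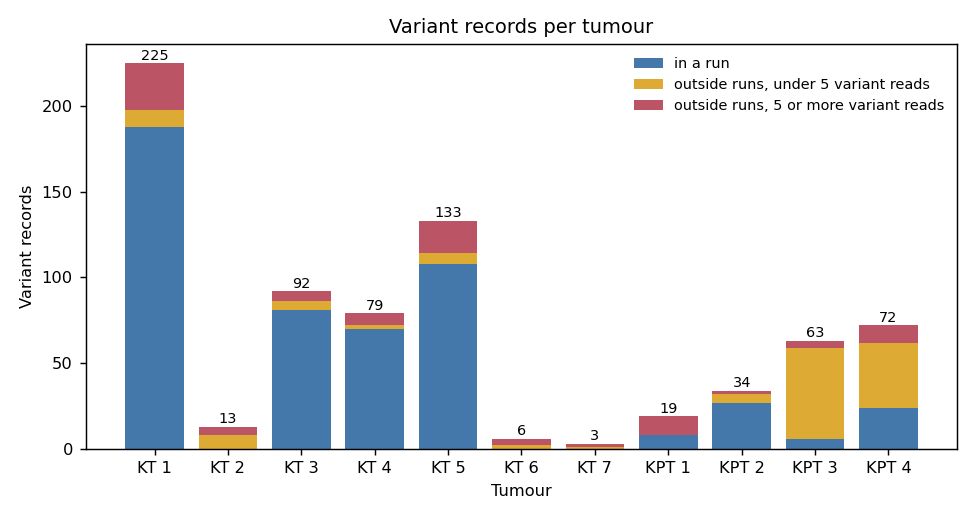
Variant records per tumour (vertical axis, number of records; the number above each bar is its total), divided into those in a chromosomal run, those outside runs with under 5 variant reads and those outside runs with 5 or more. Runs held 188 of the 225 records of KT tumour 1, and 53 of the 63 records of KPT tumour 3 lay outside runs with under 5 variant reads.

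A run was defined, after seeing the data, as at least 3 variant positions of 1 tumour with neighbours no more than 2 Mb apart. The 63 runs held 512 of the 739 records (69.3%), in 8 tumours, with 64.8% at a 1 Mb limit and 74.0% at 5 Mb. In KT tumours 447 of 551 records lay in runs (81.1%), against 65 of 188 in KPT tumours (34.6%). Per tumour the share was 48.8% ± 45.7 in KT (SD, n = 7) and 41.1% ± 29.0 in KPT (SD, n = 4), which did not differ beyond the spread (exact two-sided permutation p = 0.752).

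Runs rarely mixed allele fractions above and below 80% (1 of 63), although fractions within a run could spread widely, as from 26.5% to 70.7% in the chromosome 15 stretch of KT tumour 1. In 51 runs the median was 80% or less, and their 434 records had a median of 47.1% with quartiles of 40.4% and 53.8%. The 12 other runs had medians above 80%, and only 45 of the 2590 reads at their 78 records were reference reads (1.74%). One of these, on chromosome 17 of KT tumour 3 from 46152786 to 47372463, held 17 records with a median of 94.7%. It included Polh, the gene of a DNA polymerase that copies past damaged bases, whose Y105H change was on 91 of 91 reads. Amino acid positions here count along the protein from its first residue. KT tumour 4 had 8 such records on chromosome 1 from 105656775 to 107274993, with the protease inhibitor gene Serpinb3b, whose records the authors marked as poorly mappable, at up to 98.6%. In KPT tumour 2, 8 records of the run on chromosome 1 from 150598370 to 153240449 included 4 in Hmcn1, at a run median of 48.0%.

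**Figure D2:**
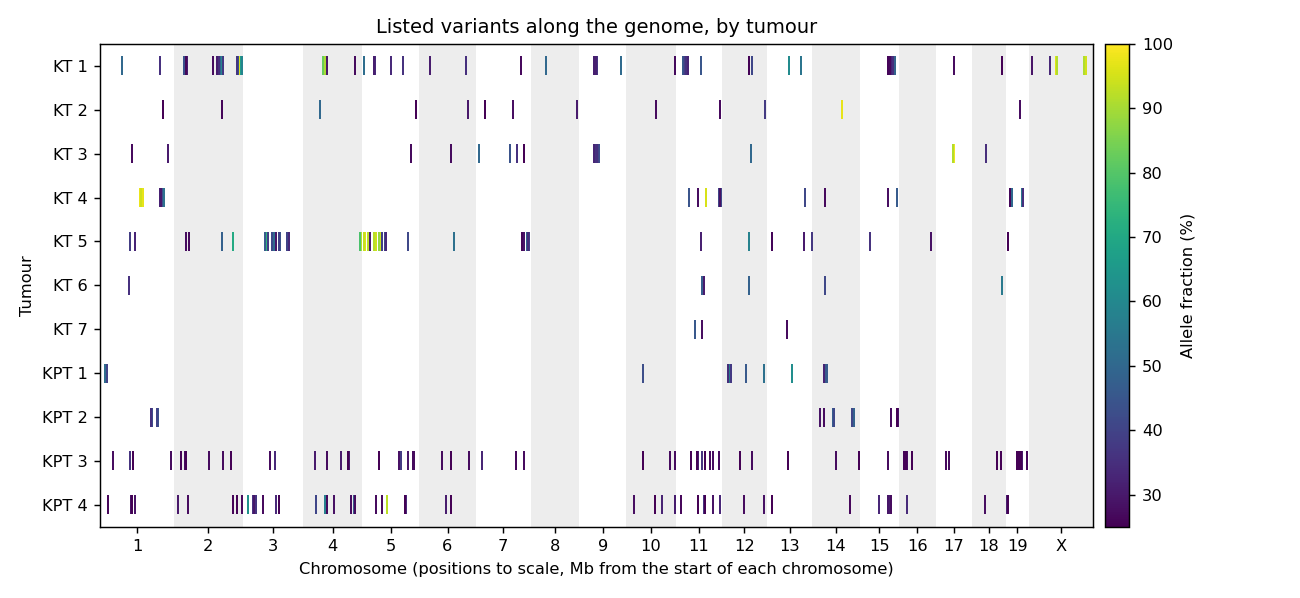
Position of each listed variant (horizontal axis, chromosomes to scale) in each tumour (vertical axis), coloured by allele fraction in percent. Clusters of like colour are visible on chromosome 9 in KT tumours 1 and 3 and chromosome 5 in KT tumour 5, while the variants of KPT tumour 3 are scattered and near 27.2%, its median.

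C-to-A changes made up much of the spectrum in KPT tumours 3 and 4, at 82.3% of 62 substitutions (95% Wilson interval 71.0% to 89.8%) and 55.7% of 70 (44.1% to 66.8%). Among the other tumours with at least 18 substitutions the share ran from 7.51% in KT tumour 1 to 22.2% in KPT tumour 1. The tumours with fewer substitutions, KT tumours 2, 6 and 7, had 54.5%, 0% and 66.7%, from 11, 6 and 3 substitutions. In KPT tumour 3, 52 of 63 records rested on 3 or fewer variant reads (82.5%), and in KPT tumour 4 it was 29 of 72 (40.3%). Jak1 P866H, with 2 of 10 reads, and Fas Q260K, with 3 of 11, were C-to-A records of KPT tumour 3.

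Between the genotypes the C-to-A share was 23.6% ± 25.9 in KT (SD, n = 7) and 43.7% ± 31.3 in KPT tumours (SD, n = 4; exact two-sided permutation p = 0.215, adjusted p = 0.645 over 6 substitution classes). Transitions, C-to-T plus T-to-C, were 55.3% ± 26.1 and 41.4% ± 24.6 of substitutions (exact p = 0.403). C-to-T changes alone were 34.1% ± 15.7 and 28.7% ± 18.0 (exact p = 0.603). Indels were 4.58% ± 5.22 and 2.41% ± 2.22 of records (exact p = 0.518). Median allele fractions were 42.1% ± 10.3 and 38.2% ± 11.4 (exact p = 0.576). None of these differences exceeded the spread between tumours, and all planned measures had an adjusted p of 0.603. The transition difference of 13.9 points rose to 23.1 points without KT tumour 7, which had 3 substitutions (exact p = 0.0476), and turned to -6.16 points without KPT tumours 3 and 4, while the C-to-T difference of 5.39 points turned to -1.49 without KPT tumour 3. The indel difference of 2.17 points turned to -5.04 at a depth of at least 20 reads and -4.75 with at least 5 variant reads, and was 0.37 without KT tumour 2, while the allele fraction difference of 3.92 points was 0.257 without KPT tumour 3 and turned to -5.79 without KPT tumours 3 and 4.

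**Figure D3:**
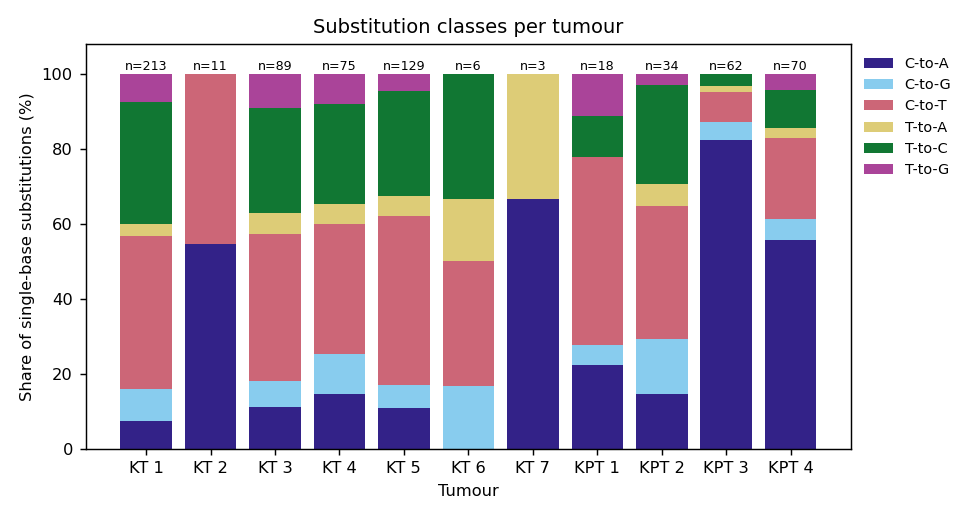
Share of each substitution class (vertical axis, percent of single-base substitutions, strands folded) per tumour, with the number of substitutions above each bar. C-to-A makes up 82.3% in KPT tumour 3 and 55.7% in KPT tumour 4, against 7.51% in KT tumour 1.

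Variants in the same gene were listed in 2 tumours for 14 genes, and in more than 2 tumours for none. On chromosome 9, KT tumours 1 and 3 shared 6 genes: the kinase gene Sik3, the ubiquitin ligase gene Ube4a, the innate immune receptor gene Nlrx1, the protease gene Tmprss13 and the olfactory receptor genes Olfr891 and Olfr895. The changes themselves differed, as in Sik3, with S1335N in KT tumour 1 (19 of 49 reads) and V970L and T992A in KT tumour 3 (27 of 58 and 22 of 57 reads). Akap9, which encodes a kinase anchoring protein, and the protease gene Hgfac were shared by KT tumours 1 and 5. The other 6 genes, among them the deacetylase gene Hdac4 and the receptor gene Lrp1, each had variants in 1 KT and 1 KPT tumour, and their KPT variants rested on 4 or fewer reads. Each of the 14 genes had a variant in a run, and 0 positions were listed in more than 1 tumour. The authors' number of samples with the same variant was 1 throughout. Whether variants found in several tumours were removed beforehand is not stated. If they were, the differing changes and the 0 shared positions were fixed in advance, and shared genes may be undercounted.

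No gene differed in frequency between KT and KPT tumours (two-sided Fisher's exact test, 0 of 14 genes past adjusted 0.05 and 0 with unadjusted p under 0.05). A gene in 2 KT and 0 KPT tumours gave an exact p = 0.491, and a gene in 2 tumours could not go below 0.109. The tumours held 572 tumour-gene pairs in 558 listed genes, each with a variant, so at most 14 genes could be shared. A uniform draw from the listed genes need not reach each of them and gave a mean of 151. The shortfall against that draw was therefore fixed in advance and decides nothing. The 14 shared genes were also set against coding genes. They compared with 30.9 under a draw by gene span from 21631 coding genes (permutation p = 0.0002, the smallest possible there) and with 6.25 under a uniform draw from the same genes (p = 0.01). Both draws picked genes independently, whereas most records lay in runs of neighbouring genes and 6 of the 14 shared genes lay together on chromosome 9. Neither p-value therefore decides whether sharing exceeded chance. Gene span also includes sequence between exons, and coding lengths were not available. The sign of the departure depended on the draw, and the number of shared genes fell to 3 without KT tumour 1, 8 without KT tumour 3, 5 at a depth of at least 20 reads, 7 with at least 5 variant reads and 0 with runs left out.

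The gene lists of pancreatic cancer pathways held few records, a share that was not tested against other genes. Those for PI3K-mTOR signalling, p53-CDKN2A-RB cell cycle control, TGF-beta-SMAD signalling and DNA repair had 0 records. They held only 17, 22, 15 and 28 genes, so 0 records does not mean that a pathway had no listed variant. Polh and Nprl3, a negative regulator of mTORC1, had records but were in none of these lists. Outside the list of very long genes, 10 of 251 listed genes had a variant, in 13 records. Among chromatin regulators, Ep300 G677E was present in KT tumour 1 (22 of 48 reads), N3581D and S2314P of the histone methyltransferase Kmt2a in KT tumour 3 (21 of 46 and 18 of 53 reads), and Tet3 G1145V in KPT tumour 4 (2 of 10 reads). The receptor gene Notch2 had S255N in KT tumour 5 (8 of 17 reads). The axon guidance ligand Slit2 had I73T, V915M and M1336V in the same tumour, on every read at each site. For Hippo signalling and adhesion, Ctnna1, the gene of alpha-catenin, had G109V in KPT tumour 4 (5 of 21 reads) and the cadherin gene Dchs1 had E317Q in KPT tumour 3 (3 of 14 reads). KPT tumour 3 also held the Jak1 and Fas changes of the immune list and R252Q in the acinar list's transcription factor Gata4 (4 of 13 reads), which the authors marked as poorly mappable.

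Of these 13 records, 7 lay in runs, 4 had 3 or fewer variant reads, and Ctnna1 G109V alone lay outside runs with at least 5. No list differed between genotypes: the Hippo and adhesion list had the smallest p, with 0 KT and 2 KPT tumours (two-sided Fisher's exact p = 0.109, adjusted p = 1 over 12 lists), and 0 lists had an unadjusted p under 0.05. Very long genes, a control for gene size, had variants in 3 KT and 3 KPT tumours (exact p = 0.545), among them Pclo and Hmcn1. Because the table starts at an allele fraction of 25%, an empty list does not exclude subclonal variants.

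The authors marked 17 records as lying in cancer genes, 15 of them in 10 tumour suppressor genes and 2 in the oncogene Abl1. The Abl1 changes were S602G and T945M in KT tumour 1. Among the suppressor genes, Elf3, an epithelial transcription factor, had S176L and D115N in KPT tumour 2 (8 of 11 and 5 of 10 reads), and the X-linked ubiquitin ligase gene Huwe1 had S1728I on 26 of 26 reads in KT tumour 1. Of the 17 records, 14 lay in runs. The marks were empty for KT tumours 2, 3 and 7.

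Truncating variants, stop gains and frameshifts, numbered 25 in 23 genes, 20 of them in 5 KT tumours and 5 in 3 KPT tumours. Per tumour this was 2.86 ± 4.26 in KT (SD, n = 7) and 1.25 ± 1.26 in KPT (SD, n = 4; exact two-sided permutation p = 0.679). KT tumour 1 had 12. There, Nprl3, a negative regulator of mTORC1, and Prr14l each had an insertion and a deletion of 1 base, 3 and 5 bases apart and with equal read numbers. Their summed length change was 0, but whether both lay on the same molecules was not tested. Without these pairs 21 truncating records were left. Outside runs and with at least 5 variant reads there were 10. In KT tumours they fell in Suv39h1, a histone H3K9 methyltransferase gene, Dnah9, Necap1, Zfp957, Myh13 and Fbln2. In KPT tumours they fell in Pias3, whose product inhibits STAT3, Lta4h, Sfmbt2 and Spata31. The Myh13 and Lta4h frameshifts, like the Prr14l pair, were marked by the authors as poorly mappable. Necap1 R48* was on 18 of 53 reads, Pias3 Q553* on 5 of 22, and the Zfp957 frameshift on 34 of 34.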

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

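All tests of explanations in this part were chosen after the patterns had been seen, and no normal tissue was used here to tell inherited from acquired variants.

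The first pattern was the gathering of variants in runs: 336 of 572 tumour-gene pairs lay in runs of at least 3 genes, against a mean of 30.6 and a highest value of 64 for randomly placed genes (permutation p = 0.001, the smallest the draws can give). Local hypermutation would make C-to-T and C-to-G changes dominate, but they were 48.4% of the substitutions in runs (44.0% to 52.8%). Reads shared between near-identical gene copies are argued against by a poor-mappability share of 9.05% (6.69% to 12.1%), for the 431 records in runs where mappability was given. Outside runs the share was 6.5%. Mappability was empty for KT tumour 3, so its chromosome 9 stretches, which include olfactory receptor genes, were not covered. Only 1 of 63 runs mixed allele fractions above and below 80%, against a mean of 34 and a lowest value of 25 when fractions were shuffled within tumours (permutation p = 0.0001, the smallest the shuffles can give). This is consistent with inherited segments of another mouse strain, heterozygous at a median of 47.1% or homozygous, as a candidate explanation that a normal sample would test. Against this, 4 runs had medians under 40%, at 25.3% and 27.1% in KPT tumour 3, 27% in KPT tumour 4 and 33.9% in KT tumour 1. Those of KPT tumour 3 held 3 records each, and that tumour had 0 records in runs at the 1 Mb limit. The run of KPT tumour 4 held 4 records with 49 reads in all, and that of KT tumour 1 held 5 records with 306 reads. The low medians of the KPT runs thus rest on few reads.

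The second pattern was the share of C-to-A calls in KPT tumours 3 and 4. In KPT tumour 4 C-to-A made up 86.2% of calls with 2 or 3 variant reads and 34.1% of the rest (two-sided Fisher's exact p = 2.1e-05), and in KPT tumour 3 it was 86.5% against 60%, from only 10 calls with more reads (p = 0.0665). The 9 other tumours had 18 C-to-A calls among 29 with few reads, where shuffling within tumours gave 5.77 (one-sided permutation p = 0.0001, the smallest possible), so errors near the reporting floor may contribute but were not settled for KPT tumour 3. Guanine oxidation during library preparation stayed open, since 57.0% of 251 variant reads had the orientation it gives (50.8% to 62.9%), between the limits set for and against it. The Trp53 genotype stayed open as well, with an exact permutation p of 0.215 and KPT tumours 1 and 2 at 22.2% and 14.7%.

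The third pattern was the set of 14 genes with variants in 2 tumours. With runs and calls under 5 variant reads left out, 0 of 93 genes were in 2 tumours, but since each of the 14 had a variant in a run, leaving out runs had to give this, and it decides nothing about their origin. For 7 of the 14 the variants lay in runs in both tumours, and those runs overlapped. KT tumours 1 and 3 overlapped on chromosome 9, with 6 of the genes. KT tumour 1 and KPT tumour 3 overlapped on chromosome 2, at Hmcn2, where the run of KPT tumour 3 held 3 records with a median of 25.3%. This KPT run was not found at the 1 Mb limit. For the other genes the variant of 1 tumour lay outside runs. Whether the overlap accounts for the sharing was not tested. The comparison of genotypes over genes gave 0 in the real split, 0 in the highest of the others and as many in 100 of 100 splits, which says nothing about chance, because no gene was in more than 2 tumours and no split could have called one.

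Values far from the rest of their group were found in 5 of 28 groups tested, where chance gives about 1 in 20. Among KT tumours, tumour 7 had a transition share of 0% and a C-to-T share of 0%, from 3 substitutions. KT tumour 2 had an indel share of 15.4%, 2 of 13 records. KT tumour 1 had 12 truncating records. Among KPT tumours, tumour 2 had a C-to-G share of 14.7%, 5 of 34 substitutions.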

How the results depend on the processing

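Of 199 alternative values, 180 kept their direction and side of the threshold (counts: within 1.5 times), though several moved severalfold in size and most had no call to lose. Leaving out runs, leaving out low-read calls with them, leaving out KPT tumours 3 and 4, and the uniform draw were chosen after seeing the data. As KT minus KPT, the variant and protein-altering differences of 31.7 turned to -15.9 without runs, and the variant difference to -0.22 on the log2 scale. The transition difference turned to -6.16 points without KPT tumours 3 and 4. The C-to-T difference turned to -3.12 without runs and calls under 5 variant reads, and to -8.56 without KPT tumours 3 and 4. The indel difference of 2.17 turned to -5.04 at a depth of 20, -4.75 at 5 variant reads and -5.19 without runs and calls under 5 variant reads, and the allele fraction difference of 3.92 to -5.79 without KPT tumours 3 and 4. Shared genes fell from 14 to 5 at a depth of 20, 7 at 5 variant reads, and 0 without runs or without runs and calls under 5 variant reads. All 14 stayed under the uniform draw, which lies below them. Filters that leave fewer records lower these counts by construction. For the other changes the cause was not tested. Leaving out each tumour gave 7.33 to 44.3 records, 3.85 to 23.1 points for transitions (exact p = 0.0476 at 23.1, without KT tumour 7; range over alternatives 0.0476 to 0.858), -1.49 (without KPT tumour 3) to 12.5 points for C-to-T, 0.37 to 3.12 for indels, 0.257 to 7.86 for allele fraction, and 3 (without KT tumour 1) to 14 shared genes, with 8 without KT tumour 3. The replicate block, which pairs tumours by a number they need not share, gave 55.2 records (exact sign-flip p = 0.375, smallest possible 0.125). With the mean substitution spectrum of each genotype subtracted, the remainders of same-numbered tumours correlated at 0.74, -0.85, -0.90 and -0.75. These are not correlations of the spectra themselves. Allele fraction minimums of 10% and 20%, positions in 1 tumour and protein-altering variants removed nothing, so they test nothing, although they count among the 180. Most values for the protein-altering load count there too, and nearly all of them repeat those for all variants. The 180 therefore overstates how much was tested. Gene and list counts stayed 0 throughout. Median depth at listed sites was 11 and 13 reads in KPT tumours 3 and 4, against 15 in KT tumour 2. Depth away from listed sites is unknown, so whether low depth limited calling in these tumours was not tested.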

Other observations

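Outside runs and with at least 5 variant reads, a set chosen after seeing the data, 97 records in 93 genes were left, 70 in KT and 27 in KPT tumours. The mean was 10 ± 9.31 per KT tumour (SD, n = 7) and 6.75 ± 4.43 per KPT tumour (SD, n = 4; exact two-sided permutation p = 0.591). Their median allele fraction was 45.8%, and 10 lay above 80%. None of the 97 carried the authors' cancer gene mark, which was empty for KT tumours 2, 3 and 7. KT tumour 7 was left with Polr2a T1222N, in the largest subunit of RNA polymerase II (19 of 66 reads), and Canx L458Q, in the chaperone calnexin (23 of 58 reads). KT tumour 6 was left with 4, Pik3r6 A726V, Six6 E214V, Sall3 T500A and Wdfy4 T411S. KPT tumour 2 was left with Slitrk1 E575D and Rnf219 M671I. KPT tumour 1 kept Adam17 P771S and V149I, in the protease that sheds epidermal growth factor receptor ligands. Both lay within 5 Mb of the end of this tumour's chromosome 12 run. At the 5 Mb limit they counted as in a run, and records in runs of KPT tumour 1 rose from 8 to 12. In KT tumour 1 the X-linked Hippo regulator Amot had M409I on 11 of 11 reads. It lay slightly more than 5 Mb from an X chromosome run of that tumour with fractions of 94.8% to 97.6%. Whether these variants belong to the runs was not tested.

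A hypothesis set before its result was seen held that variants in runs are inherited and had passed selection against truncation. Truncating variants were 7 of 512 records in runs (1.37%, 0.664% to 2.79%) and 18 of 227 outside (7.93%, 5.07% to 12.2%; two-sided Fisher's exact p = 1.85e-05). Further checks were added afterwards. Without the insertion and deletion pairs of Nprl3 and Prr14l, the shares were 5 of 510 and 16 of 225 (exact p = 1.67e-05), and among records with at least 5 variant reads they were 6 of 487 and 10 of 97 (exact p = 3.51e-05). The difference is in line with the hypothesis, but records of 1 run are not independent, and miscalled indels outside runs could give the same difference.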
